A study of Mus musculus with 4 samples.

How the data were processed

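RNA was measured on 4 Affymetrix mouse expression arrays, 2 of Atoh1-GFP cells and 2 of dNeurog1-GFP cells sorted from the neural tube of mouse embryos at E10.5. Per the labels' protocols, neural tubes were dissected between the limb levels, dissociated with trypsin and separated by GFP fluorescence on a cell sorter. Total RNA of the sorted cells was labelled by the standard Affymetrix procedure, per the labels. The labels describe the samples as GFP sorted and the 2 arrays of each population as biological replicates. They do not state outright that the arrays hold the GFP-positive cells rather than the GFP-negative ones, and the arrays are read here as GFP-positive. The number and sex of the embryos behind each sample are not given in the sources used here.

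The deposited values are MAS5 signal intensities on a linear scale, 1 column per array, and MAS5 is the only tool named in the submitters' processing notes. Its version and scaling targets are not given in the sources used here. MAS5 combines the probes of a probe set into 1 signal and multiplies each array by a constant so that its trimmed mean meets a chosen target. Over all 45101 probe sets, with 2% left out at each end, the trimmed means of the deposited intensities were 249.94 and 249.94 on the replicate 1 arrays of Atoh1-GFP and dNeurog1-GFP cells, and 499.86 and 499.87 on the replicate 2 arrays. The arrays were thus scaled to different targets by replicate number, and each target held 1 array of each population. The replicate number is therefore treated here as a processing batch, a choice made from these trimmed means before any difference between the populations was computed. The labels do not say that equal replicate numbers share a day, litter or batch.

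The 64 Affymetrix control probe sets were left out of all tests. Probe sets were kept where the mean signal over the 4 arrays was at or above the 40th percentile, a value of 42.5, which left 27022 of 45037. Of the 45037 probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 are unnamed here. Of those kept, 22889 had 1 symbol, 603 several and 3530 none. The reference gene table matched 34741 of the probe sets with 1 symbol by gene identifier and changed 0 symbols. A gene was represented by its brightest kept probe set with a single symbol, chosen by the mean over all 4 arrays, which gave 12751 genes.

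Differences were computed as Atoh1-GFP minus dNeurog1-GFP on log2(signal + 32), a scale that understates the change of dim genes. The linear models of limma 3.58.1 (lmFit and eBayes with an intensity trend) were run in R 4.3.3 with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was the threshold. The design set before the data were examined had no block. The same model with the replicate number as a block had been set beforehand as an alternative only, and giving its calls beside the others was decided from the trimmed means. List medians and the differences of selected genes are also given within the replicate 1 arrays and within the replicate 2 arrays. The log2 difference itself is the same in both models, and the block changes only its standard error. The model without the block has 2 residual degrees of freedom per gene and an infinite median prior, so its p-values rest on the spread shared across genes rather than on the gene's own. The model with the block has 1, against a median prior of 7.4, so its p-values rest on the shared spread largely.

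Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 22 lists fixed before the data were examined, and with camera at an estimated correlation and with fry as alternatives. Camera compares a list with all other genes. Fry's directional p asks whether the members of a list move, on balance, one way.

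Genes named were fixed by rule: Atoh1 and Neurog1, all measured dI1 and dI2 markers, the 12 largest called differences in each direction without overlap of the groups (filled up by unadjusted p where fewer were called), up to 4 genes of each other list, and all sex-linked genes. The rule was narrowed and widened after the data were examined. Of the other lists, mainly members that passed in either model are named, and the 12 largest differences called with the block were added in each direction. Further list members given as examples, and 5 further lists with the ribosomal protein genes, were also chosen after the data were examined.

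The statistics were tested on simulated data with the real genes, means and spreads, with 100 genes changed by 1 log2 unit and 100 by 2, in 20 simulations. The simulated values kept each gene's difference between replicate numbers, and their noise came from the model with the block. They thus assume that the block is right and cannot show whether it is justified. Without the block, a mean of 0.2 of the 100 smaller and 15.85 of the 100 larger gene changes were recovered, with 0 false calls. With the block, 89.2 and 100 were recovered, and 12.9% of all gene calls were false, above the nominal 5%. For probe sets the recovered means were 0 and 18.75 without the block and 81.75 and 99.95 with it, and 11.0% of the calls with the block were false. In 1 simulation with a list shifted by 0.6 log2 units, camera at the preset correlation called the list in both models and also 2 unshifted lists without the block and 1 with it. An estimated correlation missed the shifted list, with adjusted p = 0.99 without the block and 0.85 with it. Fry missed it too, with adjusted p = 0.99 without the block and 0.23 with it. A list that fails with an estimated correlation or with fry is therefore not argued against by that failure.

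Alternatives tried were quantile normalization, scaling to one 75th percentile or one trimmed mean, pseudocounts of 1 and 100, no filter or a 60th percentile filter, no intensity trend, the mean of a gene's probe sets, an unadjusted threshold with a 2-fold change, and each array left out in turn. The precision of every value is limited by the 2 arrays per population. Over the 45037 probe sets, 0 values were identical between any pair of arrays, so each array was counted as its own sample. Probe-level data and the ChIP-seq data of the same study were not analysed here.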

Results

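Gene expression was profiled in 2 populations of GFP-sorted cells from the mouse neural tube at E10.5. The sources used here do not state outright that the arrays hold the GFP-positive cells of the sort. In Atoh1-GFP embryos, a bacterial artificial chromosome carrying the Atoh1 locus places GFP in the cells that form dorsal interneuron 1 (dI1). In dNeurog1-GFP embryos, a Neurog1 enhancer places GFP in the neighbouring dorsal cells that form dorsal interneuron 2 (dI2). Each population was measured on 2 arrays from biological replicates, and 12751 genes were tested. The median deposited signals were 69.1 and 76.0 on the Atoh1-GFP arrays and 57.4 and 75.4 on the dNeurog1-GFP arrays. The replicate 1 and replicate 2 arrays had been scaled to trimmed means of 249.94 and 499.86 in Atoh1-GFP cells, and to 249.94 and 499.87 in dNeurog1-GFP cells. Calls are therefore given without and with the replicate number as a block, and list medians and selected genes also within each replicate number.

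The question of the comparison was which genes distinguish the Atoh1-derived dI1 population from its dI2 neighbours. Atoh1, the basic helix-loop-helix factor that specifies dI1, had signals of 10706 and 19675 in Atoh1-GFP cells and 886 and 1861 in dNeurog1-GFP cells. Its log2 difference was 3.46, with 3.55 within replicate 1 and 3.38 within replicate 2. Whether this probe set also reads transcripts of the transgene is not given in the sources used here. Neurog1, the basic helix-loop-helix factor of the dI2 domain, had signals of 86.1 and 176 in Atoh1-GFP cells and 694 and 2469 in dNeurog1-GFP cells, a log2 difference of -3.10 (-2.62 within replicate 1 and -3.59 within replicate 2). Without the block both genes missed the threshold (limma adjusted p = 0.23 for each, standard errors 1.01 and 0.90). With the block both passed it, at adjusted p = 1.6e-05 (standard error 0.12) for Atoh1 and 2.7e-04 (0.23) for Neurog1.

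The other dI1 transcription factors followed Atoh1. Lhx2 and Lhx9, LIM-homeodomain factors of dI1 neurons, were higher in Atoh1-GFP cells by 3.13 and 2.64 log2 units, and the Bar-class homeodomain factors Barhl1 and Barhl2 by 2.77 and 3.03. All 5 dI1 markers passed the threshold with the block and 0 without it, while 5 passed in either model when adjusted over the list alone. The median of the list was 3.03 (3.09 within replicate 1 and 3.18 within replicate 2). Camera gave adjusted p = 5.2e-25 without the block and 6.9e-12 with it. With an estimated correlation the adjusted p was 0.41 without the block and 0.54 with it. That setting called 0 of the 22 lists in either model and missed the shifted list of the simulation. Its values, here and for the lists below, therefore cannot decide whether a list differs.

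Among the dI2 markers, Neurog2 was lower in Atoh1-GFP cells by a log2 difference of -3.57, and the LIM-homeodomain genes Lhx1 and Lhx5 by -2.98 and -2.15. With the block, 4 of the 6 markers passed the threshold over all genes and 5 when adjusted over the list alone, and without the block 0 and 4 did. Foxd3 had a log2 difference of -1.15 (adjusted p = 0.060 with the block) and Foxp2 one of 0.12 (adjusted p = 0.67). The list median was -2.57, with -2.07 within replicate 1 and -2.96 within replicate 2. Camera gave adjusted p = 2.2e-20 without the block and 7.4e-07 with it. An estimated correlation gave adjusted p = 0.41 and 0.54.

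**Figure D1:**
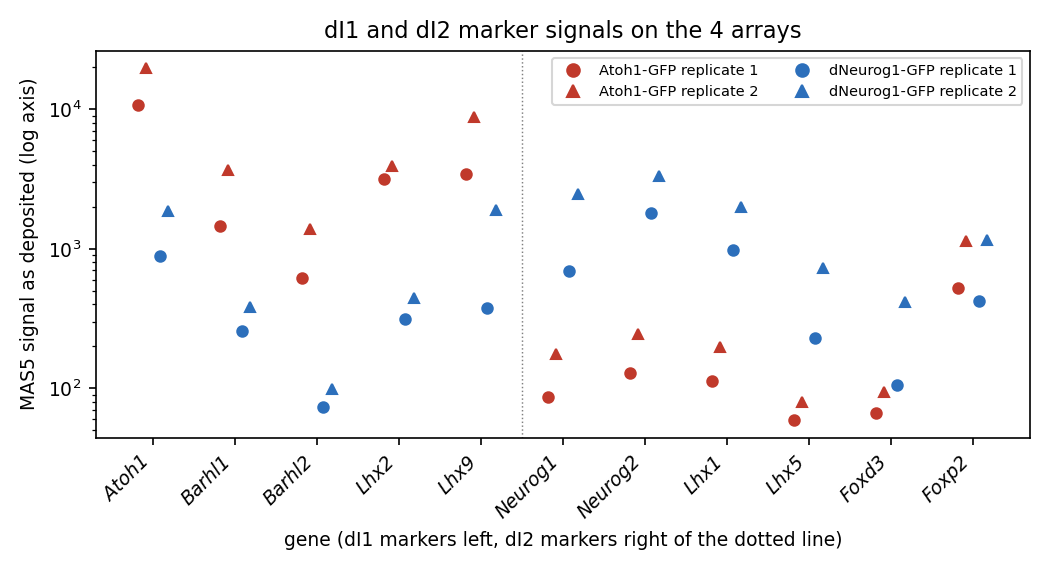
Deposited MAS5 signals (vertical log axis) of the 5 dI1 and 6 dI2 marker genes (horizontal axis), 1 point per array, circles for replicate 1 and triangles for replicate 2, red for Atoh1-GFP and blue for dNeurog1-GFP cells. Both Atoh1-GFP arrays lie above both dNeurog1-GFP arrays for the 5 dI1 markers, and Foxp2 overlaps, with 520 and 1131 against 424 and 1156.

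Over all genes, 13 of 12751 passed the threshold without the block, 2 higher in Atoh1-GFP and 11 higher in dNeurog1-GFP cells. Rmst, a long non-coding RNA, was higher in Atoh1-GFP cells by 2.81 log2 units (standard error 0.69, adjusted p = 0.049; 1.51 within replicate 1 and 4.11 within replicate 2). Myh6, a cardiac myosin heavy chain, was higher by 1.98 (adjusted p = 0.018), with signals of 43.2 and 498 against 17.6 and 19.8. Its difference lay mainly in replicate 2 (3.36, against 0.60 in replicate 1) and missed the threshold with the block (adjusted p = 0.056). Higher in dNeurog1-GFP cells were the secreted factor gene Scube2 (-3.64), Fam181a (-2.57), the homeodomain genes Gsx1 (-2.57) and Lhx4 (-2.57), and the progenitor factor Olig2 (-2.30). Also higher there were Gad1 (-2.40) and Slc32a1 (-1.62), which make and package the transmitter GABA, Pdzph1 (-1.99), Vit (-1.93), Olfm4 (-1.91) and Tfap2e (-1.86). Adjusted p of these 11 genes ranged from 6.0e-05 for Gsx1 and Olig2 to 0.025 for Olfm4, and each also passed with the block. These adjusted p do not rank the genes above brighter ones. The spread without the block includes the difference between the scaling targets, which the pseudocount damps for dim genes. The standard error without the block was 0.44 for Gsx1 and 0.40 for Olig2, against 1.01 for Atoh1 and 1.04 for Lhx2. As deposited, all 11 genes differed more within replicate 2 than within replicate 1, most unevenly Olig2 (-1.02 within replicate 1 and -3.59 within replicate 2), Gad1 (-1.32 and -3.48) and Lhx4 (-1.65 and -3.48). The pseudocount shrinks dim signals more on the replicate 1 arrays, which had the lower target, so this order is not read as a replicate effect for all 11. On one trimmed mean Olig2 had 3.82 and 7.45 in Atoh1-GFP and 73.6 and 443 in dNeurog1-GFP cells. Lhx4 had 22.8 and 6.55 against 209 and 399.

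This short list depended on scaling and on single arrays. On one trimmed mean 29 genes passed, 17 higher in Atoh1-GFP and 12 higher in dNeurog1-GFP cells, and after quantile normalization 25 passed, 16 and 9. Scaling to one 75th percentile gave 24, split 11 and 13. Without the Atoh1-GFP replicate 1 array 1 gene passed, without Atoh1-GFP replicate 2 0 did, without dNeurog1-GFP replicate 1 25 did and without dNeurog1-GFP replicate 2 2 did. At an unadjusted p under 0.05, limma counted 242 genes without the block. At the level of probe sets, 32 of 27022 passed, 12 higher in Atoh1-GFP and 20 in dNeurog1-GFP cells.

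With the replicate number as a block, 1188 genes passed, 512 higher in Atoh1-GFP and 676 higher in dNeurog1-GFP cells, and 12 of the 13 genes above were among them. Of the 1188, 203 were at least 2-fold higher in Atoh1-GFP and 210 in dNeurog1-GFP cells. Most calls thus exist only with the block, which leaves 1 residual degree of freedom. In simulated data that assume the block to be right, 12.9% of the calls of this model were false. For probe sets the block gave 2399 calls, 1212 higher and 1187 lower in Atoh1-GFP cells. Without any model, 129 genes were at least 2-fold higher in Atoh1-GFP cells within both replicate numbers, 137 were at least 2-fold higher in dNeurog1-GFP cells within both, and 5 went opposite ways. Across genes, which are not independent replicates, the differences within the replicate numbers correlated at Pearson's r = 0.57 and Spearman's rho = 0.49.

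Beyond the dI1 markers and Rmst, the largest differences toward Atoh1-GFP cells called with the block were in Gm8350 (2.96), the G protein subunit Gng4 (2.75), Rassf4 (2.66), the membrane-anchored semaphorin Sema7a (2.48), Pdzrn4 (2.45) and Gsg1l (2.28). Toward dNeurog1-GFP cells they included the secreted factor Ndnf (-3.0), the AP-2 transcription factors Tfap2b (-3.0) and Tfap2a (-2.69), the basic helix-loop-helix factor Ptf1a (-2.62) and the Iroquois factor Irx3 (-2.62). Adjusted p with the block ran from 5.8e-05 for Tfap2b and Irx3 to 0.0043 for Ptf1a. None of these 11 genes passed without the block. In order of unadjusted p without the block, the 10 genes after Rmst and Myh6 on the Atoh1-GFP side were Lrrn2 (1.51), Ralyl (1.5), Fam163a (2.14), Cdkn2b (1.57), Myl7 (2.15), Barhl2, Sstr3 (1.84), Ppbp (1.70), Epha8 (2.18) and Atoh1, and the gene after the 11 called ones on the other side was Skor1 (-2.46). They missed the threshold without the block, with adjusted p from 0.10 to 0.23, and passed with it.

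**Figure D2:**
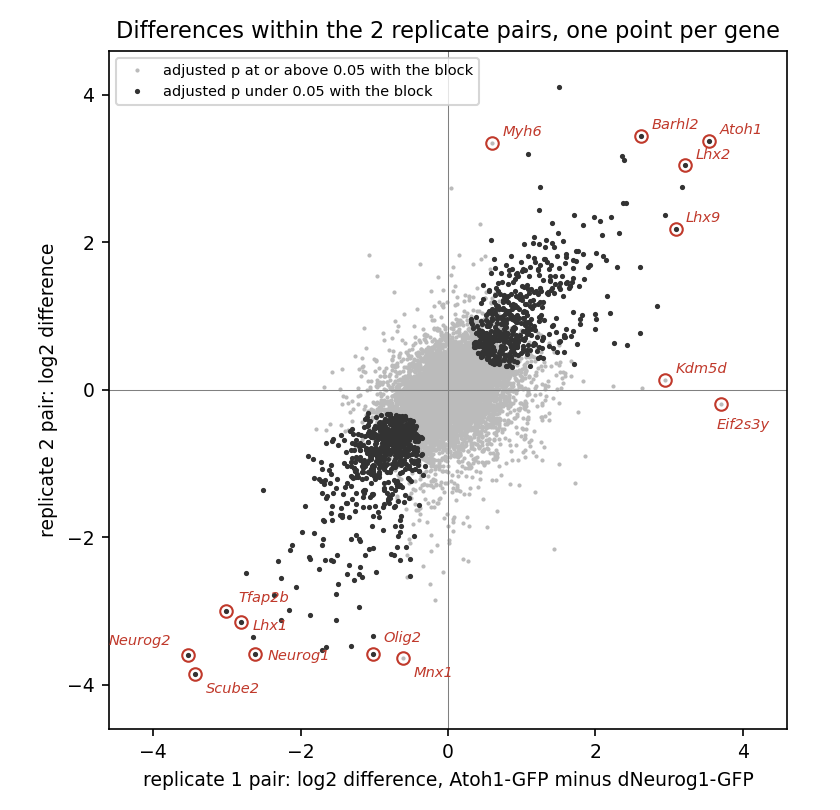
Log2 difference (Atoh1-GFP minus dNeurog1-GFP) of each of the 12751 genes within the replicate 1 arrays (horizontal axis) and within the replicate 2 arrays (vertical axis), dark where the adjusted p with the block was under 0.05. Atoh1 lies at 3.55 and 3.38 and Scube2 at -3.43 and -3.86, whereas Mnx1 (-0.61 and -3.64), Myh6 (0.60 and 3.36) and Eif2s3y (3.70 and -0.20) differ mainly within 1 replicate number.

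Several markers of the more ventral dorsal interneurons, dI3 to dI6, were lower in Atoh1-GFP cells. With the block 7 of 13 measured members passed, all lower, and adjusted over the list alone 8 passed with the block and 7 without it. They included Gsx2 (-2.11) and Gsx1 of the Gsx progenitor domain, Ptf1a of the inhibitory dI4 lineage, Lbx1 (-1.86) and Isl1 (-2.32). Isl1 had -1.51 within replicate 1 and -3.12 within replicate 2, Ptf1a -1.71 and -3.53, and Lbx1 -1.34 and -2.38. These 3 thus differed more within replicate 2, where the ventral neural tube markers also differed. Gsx2 had -2.11 within both, and Gsx1 -2.36 and -2.78. The list median was -1.31 (-0.74 within replicate 1 and -1.46 within replicate 2), and camera gave adjusted p = 1.4e-27 without the block and 9.3e-07 with it. The adjusted p became 0.41 and 0.54 with an estimated correlation. Of 10 factors shared by several dorsal domains, the paired-box genes Pax7 (-1.93) and Pax3 (-1.49) were lower in Atoh1-GFP cells with the block, and 8 did not pass, while 4 passed, all lower, when adjusted over the list alone. That list as a whole did not pass (median -0.12, -0.26 within replicate 1 and -0.02 within replicate 2; camera adjusted p = 0.13 in both models). Among 9 roof plate markers, Wnt3a (1.13) and Bmp7 (0.72) were higher and Gdf10 (-1.35) was lower in Atoh1-GFP cells with the block (2 and 2 when adjusted over the list alone), and the list did not pass (median -0.01, 0.37 within replicate 1 and -0.33 within replicate 2; adjusted p = 0.59 without the block and 0.95 with it).

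Ventral neural tube markers differed between the replicate numbers. Their median was 0.01 within replicate 1 and -1.24 within replicate 2, -0.64 together, and camera gave adjusted p = 1.4e-18 without the block and 0.0067 with it. It became adjusted p = 0.41 without and 0.75 with the block at an estimated correlation. With the block, Olig2 and Lhx4 were lower and Evx1 (1.69) was higher in Atoh1-GFP cells, and 18 of 21 members did not pass. Adjusted over the list alone, 1 was higher and 6 were lower with the block, and 8 passed without it. Olig2 had a log2 difference of -1.02 within replicate 1 and -3.59 within replicate 2, and the motor neuron factor Mnx1 had -0.61 and -3.64 (adjusted p = 0.053 with the block). The mesenchyme and muscle list moved between the replicate numbers in the same direction, with a median of 0.65 within replicate 1 and -0.40 within replicate 2.

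Many genes of dividing progenitors were lower in Atoh1-GFP cells. With the block 24 of 37 cell cycle genes passed, all lower, and 35 when adjusted over the list alone, whereas 0 passed without it on either adjustment. The replication licensing factors Cdc6 (-1.57) and Cdt1 (-1.30), the replicative helicase subunit Gins2 (-1.15) and cyclin E2, Ccne2 (-1.08), were among them, as were Mcm3 (-1.10) and Birc5 (-0.94). The list median was -0.64 within replicate 1 and -0.63 within replicate 2. Camera gave adjusted p = 8.1e-08 without the block and 7.8e-22 with it. The call did not hold with an estimated correlation (adjusted p = 0.72 and 0.54). Of 24 neural progenitor genes 12 passed with the block, all lower in Atoh1-GFP cells, and 16 when adjusted over the list alone. The SoxB factors Sox1 (-1.72), Sox3 (-1.32) and Sox21 (-1.94), Pax6 (-1.58), Fabp7 (-1.48) and Ttyh1 (-1.04) were among them. The median was -0.63 (-0.71 within replicate 1 and -0.55 within replicate 2), and camera gave adjusted p = 5.6e-07 without the block and 1.9e-09 with it. With an estimated correlation the adjusted p was 0.61 and 0.54.

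Of the neurogenic and neuronal genes called with the block, more were higher than lower in Atoh1-GFP cells. Of 30 Notch ligands and neurogenic genes, 11 were higher and 4 lower with the block and 15 did not pass, and 14 were higher and 4 lower when adjusted over the list alone. The early neuronal factors Ebf3 (1.60), Ebf1 (1.41) and Ebf2 (1.33) and Insm1 (1.16), Dll3 (1.06) and Hes6 (1.05) were among the higher ones, and Jag1 (-0.69), Neurod1 (-0.65), Neurod4 (-0.57) and Notch3 (-0.51) were the lower ones. The median was 0.39 (0.42 within replicate 1 and 0.39 within replicate 2), with camera adjusted p = 0.011 without the block and 4.3e-05 with it. An estimated correlation gave adjusted p = 0.83 and 0.54. Of 34 pan-neuronal genes 13 were higher and 2 lower with the block and 19 did not pass, and 19 were higher and 4 lower when adjusted over the list alone. Tubulin beta 3, Tubb3 (1.01), doublecortin, Dcx (0.99), and Syt4 (0.83) were higher, while the neurofilament genes Nefm (-0.78) and Nefl (-0.71) were lower. The median was 0.40 (0.53 within replicate 1 and 0.32 within replicate 2), with camera adjusted p = 0.021 without the block and 2.9e-06 with it. The adjusted p became 0.84 and 0.59 with an estimated correlation. No member of either list passed without the block.

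Axon guidance genes went both ways. With the block 10 of 49 were higher and 10 lower in Atoh1-GFP cells, and 14 and 14 when adjusted over the list alone, where 1 passed without the block. The ephrin receptors Epha8 and Epha5 (2.09), the adhesion molecule Cntn2 (1.96), the semaphorin receptor Nrp2 (1.13) and the netrin receptor Dcc (0.94) were higher. Epha3 (-1.67) and netrin 1, Ntn1 (-1.56), were lower. The list did not pass (median 0.11, 0.31 within replicate 1 and -0.18 within replicate 2; camera adjusted p = 0.99 without the block and 0.70 with it).

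Transmitter genes also went both ways. Slc17a6, the vesicular glutamate transporter, was higher in Atoh1-GFP cells by 1.98 log2 units (adjusted p = 5.6e-04 with the block, 2.30 within replicate 1 and 1.66 within replicate 2). The inhibitory genes Gad1, Gad2 (-1.24), Slc32a1 and the glycine transporter Slc6a5 (-1.22), and somatostatin, Sst (-1.72), were lower with the block. As deposited, their differences were larger within replicate 2, where the ventral neural tube markers also differed: Gad1 had -1.32 and -3.48, Gad2 -0.64 and -1.85, Slc32a1 -1.19 and -2.05, Slc6a5 -1.03 and -1.41 and Sst -0.97 and -2.47 within replicates 1 and 2. The pseudocount shrinks dim signals more on the replicate 1 arrays, so this order is not read as a replicate effect for all of them. On the dNeurog1-GFP arrays, scaled to trimmed means of 249.94 and 499.87, Slc32a1 had deposited signals of 58.2 and 114 and Slc6a5 95.8 and 109. Gad2 had 72.3 and 174 there, and Gad1 117 and 536. These were 1 higher and 5 lower of 13 members, and 2 and 6 when adjusted over the list alone, where 4 passed without the block. The list passed without the block (median -0.37, -0.31 within replicate 1 and -0.56 within replicate 2; camera adjusted p = 1.5e-10) and not with it (adjusted p = 0.081). It became adjusted p = 0.41 without and 0.82 with the block at an estimated correlation.

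Anterior Hox genes, paralogue groups at the 3' end of the clusters, included several that were higher in Atoh1-GFP cells. With the block 7 of 13 passed, all higher, and 9 when adjusted over the list alone, among them Hoxa5 (0.92), Hoxb5 (0.79) and Hoxa3 (0.73). The median was 0.54 (0.50 within replicate 1 and 0.64 within replicate 2), and camera gave adjusted p = 0.0095 without the block and 4.9e-07 with it. The call did not hold with an estimated correlation (adjusted p = 0.76 and 0.54). The posterior Hox list (median -0.28, 0.17 within replicate 1 and -0.17 within replicate 2) passed without the block, at adjusted p = 0.032, and not with it, at 0.71. With an estimated correlation the adjusted p was 0.83 and 0.92. Of its 15 members 2 were higher and 1, Hoxd9 (-1.16, -0.73 within replicate 1 and -1.59 within replicate 2), was lower with the block. Among the members with the smallest unadjusted p without the block, Hoxd10 (0.20 and -2.29), Hoxc10 (-0.01 and -1.69) and Hoxd11 (0.67 and -1.65) did not pass with the block. They were lower in Atoh1-GFP cells mainly within replicate 2. On the dNeurog1-GFP arrays Hoxd10 had deposited signals of 45.1 and 805 and Hoxc10 56.8 and 1047. Among 15 genes that respond to BMP, Wnt or retinoid signals, Smad7 (1.99) and Nkd1 (1.70), feedback inhibitors of those pathways, were higher with the block, while Sp5 (-1.76) and Rarb (-1.08) were lower. In all 5 were higher and 2 lower, and 6 and 2 when adjusted over the list alone, where 1 passed without the block. The list did not pass (median 0.10, 0.20 within replicate 1 and 0.10 within replicate 2; camera adjusted p = 0.59 without the block and 0.060 with it).

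Markers of other cell types were also compared. Of 13 neural crest and sensory ganglion markers 6 were lower and 1 higher in Atoh1-GFP cells with the block (median -0.28, -0.47 within replicate 1 and -0.84 within replicate 2; camera adjusted p = 3.0e-07 without the block and 0.0032 with it). An estimated correlation gave adjusted p = 0.41 and 0.54. Adjusted over the list alone the counts with the block were the same, and 4 passed without it. The lower ones included Tfap2a, Tfap2b, Ret (-1.86) and Prph (-1.50), genes that also act in neurons, whereas the glial crest factor Sox10 had a log2 difference of 0.30 (adjusted p = 0.49 with the block). Ret (-1.17 and -2.54) and Prph (-0.77 and -2.23) differed more within replicate 2 than within replicate 1, as did Tfap2a (-2.26 and -3.12). Tfap2b had -3.01 and -2.99. Several blood markers were higher in Atoh1-GFP cells. With the block 5 of 10 passed, and adjusted over the list alone 7 passed with the block and 2 without it. The 5 were the embryonic globins Hba-x (1.52), Hbb-bh1 (1.44) and Hbb-y (1.03) and the myeloid genes Tyrobp (1.13) and Csf1r (0.91). Hbb-y reached signals of 8685 and 17478 in Atoh1-GFP and 2624 and 13725 in dNeurog1-GFP cells. The blood median was 1.20 within replicate 1 and 0.65 within replicate 2, with camera adjusted p = 9.9e-11 without the block and 6.2e-05 with it. The adjusted p became 0.41 and 0.54 with an estimated correlation.

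Of 13 endothelial markers 0 passed in either model, on either adjustment. Their median was 0.61 (0.82 within replicate 1 and 0.26 within replicate 2), and camera gave adjusted p = 4.4e-07 without the block and 0.0016 with it. It became adjusted p = 0.42 without and 0.75 with the block at an estimated correlation. Of 23 mesenchyme and muscle markers 0 passed, and the list did not pass (median 0.11, as above within each replicate number; adjusted p = 0.21 without the block and 0.26 with it). Of 8 epidermis markers Grhl3 (1.81) was higher with the block, as when adjusted over the list alone, where 1 also passed without it, and the list call (median 0.22, 0.49 within replicate 1 and 0.01 within replicate 2; adjusted p = 0.0066) was lost with it, at 0.076. The call did not hold with an estimated correlation (adjusted p = 0.41 and 0.54). Of 16 stress and dissociation genes 1, Jun (-0.80), was lower with the block, and the list did not pass (median 0.12, 0.21 within replicate 1 and 0.06 within replicate 2; adjusted p = 0.59 without the block and 0.64 with it).

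The sex-linked genes separated 1 array from the others. On one trimmed mean the Y-linked gene Eif2s3y had signals of 795 and 839 in Atoh1-GFP cells and 1.88 and 968 in dNeurog1-GFP cells. Uty had 465, 354, 21.0 and 348, and Kdm5d had 513, 851, 10.7 and 769, in the same order, so dNeurog1-GFP replicate 1 was lowest for all 3. Xist, transcribed from the inactive X chromosome, had a log2 difference of 0.02 at its brightest probe set. None of the 4 genes passed in either model over all genes, but the 3 Y-linked genes were higher in Atoh1-GFP cells with the block when adjusted over the list alone, and 0 without it. The list call (median 1.44, 2.79 within replicate 1 and 0.08 within replicate 2; camera adjusted p = 5.1e-06) was lost with the block, at adjusted p = 0.060. With an estimated correlation the adjusted p was 0.41 and 0.54.

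**Figure D3:**
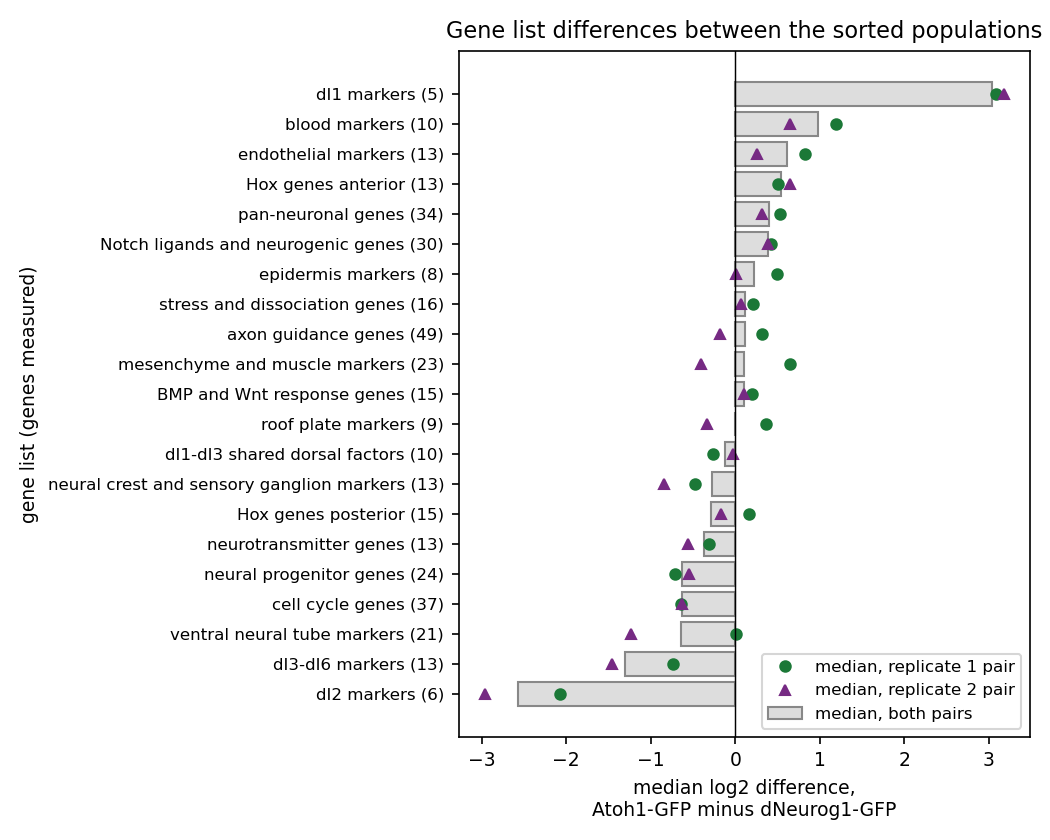
Median log2 difference (horizontal axis, Atoh1-GFP minus dNeurog1-GFP) of 21 gene lists, with the number of measured genes in parentheses, as bars over both replicate numbers and as points within replicate 1 (green circles) and replicate 2 (purple triangles). The cell cycle medians coincide (-0.64 and -0.63), whereas the ventral neural tube medians lie at 0.01 and -1.24.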

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

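The alternatives that join the replicate block to another change, and scaling to one trimmed mean, were chosen after seeing the data, and the others before. Replicate numbers of 2 arrays per population cannot show by themselves that arrays are paired, and the deviations from the population means of same-numbered arrays correlated across probe sets at 0.77 as deposited and 0.72 on one trimmed mean. With the replicate block 2399 probe sets and 1188 genes passed, against 32 and 13 without it. Without the block, counts of probe sets and genes were 1 and 25 after quantile normalization, 1 and 24 at one 75th percentile, 1 and 29 on one trimmed mean, 62 and 25 with a pseudocount of 1, 14 and 8 with 100, 2 and 0 with the 60th percentile filter, 0 and 3 without the trend, and 456 and 183 at an unadjusted p with a 2-fold change. Without a filter 0 probe sets and 10 genes passed, and the mean of a gene's probe sets gave 28 genes. Joined to the block, they were 2098 and 1859 after quantile normalization, 2110 and 854 on one trimmed mean, 1943 and 951 with a pseudocount of 1, 2711 and 1246 with 100, 629 and 490 without a filter, 1880 and 1038 with the 60th percentile filter and 587 and 245 without the trend, and 1047 genes with the mean of probe sets. Of the 1188 genes, 1187 were also called after quantile normalization, 854 on one trimmed mean and 245 without the trend. Leaving out 1 array at a time without the block, which sets arrays of different scale against each other and assumes that the lone array varies like the others, gave 0 to 23 probe sets, 0 to 25 genes and 11 to 16 lists. Of the 22 lists 16 passed without the block and 12 with it, 0 with an estimated correlation in either model, and with fry 0 without the block and 1, the dI1 markers (adjusted p = 0.037), with it. Over all alternatives the named genes kept their direction and side of the threshold in 1617 cases, gained a call in 874, lost one in 123 and changed sign in 28, and lists did so in 423, 6, 121 and 22. Among lists, the direction changed for roof plate markers (0.026 after quantile normalization, -0.019 at the 75th percentile, 0.16 with the 60th percentile filter with and without the block, 0.0012 on one trimmed mean, -0.0040 with the block and a pseudocount of 1, and -0.0078 with the block and fry). It also changed for posterior Hox genes (-0.29 after quantile normalization, and with the block -0.042 without a filter and -0.049 with the 60th percentile filter) and axon guidance genes (0.076 with a pseudocount of 100 and 0.11 without a filter). For stress genes it changed at 0.045 without a filter, 0.019 with the 60th percentile filter and -0.086 with the block and the mean of probe sets. These are medians, whose sign can differ from that of the test. Among genes, Xist turned to -8.7e-04 at the 75th percentile and to -0.16 with the mean of probe sets in both models, and Sox10 to -0.053 with that mean in both models. With 1 array left out, the direction changed, over these ranges, for Foxp2 (-0.57 to 0.81), Hoxd9 (-2.89 to 0.57), Xist (-0.45 to 0.49), Eif2s3y (-0.71 to 4.21), Uty (-0.25 to 2.91), Kdm5d (-0.67 to 3.76), Hbb-bh1 (-0.021 to 2.91), Hbb-y (-0.16 to 2.22), Pfkl (-1.33 to 0.14), Dhcr7 (-1.25 to 0.12), Tnnc1 (-0.15 to 2.01), Nefl (-1.57 to 0.15), Jag1 (-1.52 to 0.13), Neurod1 (-1.57 to 0.27) and Neurod4 (-1.93 to 0.78). The same holds for the lists of axon guidance (-0.53 to 0.54), shared dorsal (-0.57 to 0.094), mesenchyme and muscle (-0.77 to 0.92), roof plate (-0.47 to 0.37), posterior Hox (-1.13 to 0.90) and BMP and Wnt response genes (-0.17 to 0.68). With 1 array left out the different scaling targets enter the difference, and within both replicate numbers Pfkl (-0.66 and -0.53) and Dhcr7 (-0.63 and -0.50) kept their sign. Beyond this, the cause of these changes was not tested. Dim genes are limited by the pseudocount, which shrinks differences at signals near or under 32.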

Other observations

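The tests in this part were chosen after the results they bear on were seen, except those on motor neuron, sterol and ribosomal protein genes, which were chosen before their values were seen. The glycolysis and hypoxia list was chosen after Slc2a1 was seen, and its test leaves that gene out. Iroquois and heart muscle genes were chosen for their values, so no list test is given for them. Of 5 measured Iroquois homeodomain genes, which pattern the neural tube along its dorsoventral axis, Irx3, Irx5 (-1.96) and Irx2 (-0.85) were lower in Atoh1-GFP cells with the block. Of 12 heart muscle genes Myl7, Myl4 (1.81), Tnnt2 (1.07) and Tnnc1 (0.93) were higher there with the block, and the other 8 did not pass. Myl7 differed mainly within replicate 2 (3.20, against 1.09 within replicate 1). Within replicates 1 and 2 Myl4 had 1.93 and 1.69, Tnnt2 1.37 and 0.76, and Tnnc1 1.08 and 0.78.

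Slc2a1, the glucose transporter of embryonic tissue, had a log2 difference of -1.48 and passed with the block. The other 14 glycolysis and hypoxia genes had a median of -0.24 (camera adjusted p = 0.0024 with the block, 0.17 without it, and 0.29 with the block and an estimated correlation), and 1 of them passed with the block, Pfkl (-0.60). Sterol synthesis genes had a median of -0.38 (adjusted p = 7.6e-04 with the block, 0.13 without it, and 0.30 with the block and an estimated correlation), and 2 of 11 passed, Idi1 (-0.60) and Dhcr7 (-0.56). The 43 ribosomal protein genes did not pass (median 0.13, adjusted p = 0.24 with the block).

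Arrays with the same replicate number resembled each other more than arrays of the same population: over the kept probe sets Pearson's r was 0.957 and 0.968 between the populations within replicates 1 and 2, and 0.934 and 0.948 between the replicates of Atoh1-GFP and of dNeurog1-GFP cells. The scaling targets alone do not account for this, since a constant factor leaves the ranks on an array unchanged. Spearman's rho was 0.939 and 0.960 between the populations within replicates 1 and 2, against 0.913 and 0.930 between replicates. On one trimmed mean the deviations of the populations still correlated across genes at 0.64, a weak test, since rescaling acts on it only through the pseudocount. The log2 distance between the 25th and 75th percentiles, which rescaling does not change, was 3.63 and 3.88 on the replicate 1 arrays and 4.80 and 4.83 on the replicate 2 arrays (Atoh1-GFP first). A different sex mix stays open: the Atoh1-GFP arrays differed by at most 0.70 log2 units at a Y-linked gene and by -0.05 (replicate 2 minus 1) at the brightest Xist probe set, but another Xist probe set changed by -3.54 in Atoh1-GFP and -3.47 in dNeurog1-GFP cells, and Y-linked genes rose in dNeurog1-GFP cells. A difference in RNA integrity or labelling between replicate numbers may contribute and stays open: the lowest 3' to 5' ratio of beta-actin on a replicate 2 array lay 0.63 above the highest on a replicate 1 array, and for Gapdh the gap was 0.095, over 2 arrays each. No biological explanation other than the sex mix was tested for this.

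Ventral neural tube genes were high on the dNeurog1-GFP replicate 2 array, the highest of the 4 arrays for 13 of 21 members. A batch difference that raised them alike on both replicate 2 arrays is argued against: on one trimmed mean their median change from replicate 1 to 2 was -0.57 log2 units in Atoh1-GFP cells (SD 0.55 over members, 18 of 21 falling) and 0.77 in dNeurog1-GFP cells (SD 0.89, 17 rising), with 1 array behind each level. The sign of the Atoh1-GFP change depends on the scale. Over all kept probe sets and both populations the median change was 0.75 as deposited and -0.13 on one trimmed mean. The gap between the populations does not rest on that sign. As deposited, the median difference of the ventral list was 0.01 within replicate 1 and -1.24 within replicate 2. RNA of motor neurons could not be decided, with a median excess of 0.33 over 3 genes outside the lists (Alcam, Ngfr and Chodl), taken as the change in dNeurog1-GFP less that in Atoh1-GFP cells, for which a sign-flip p cannot be smaller than 0.25. RNA of other trunk cells, which dissection and sorting would be meant to remove, may be part of it and stays open: the same excess was 1.39 for the ventral list, 1.37 for mesenchyme and muscle, 0.86 for endothelial, 0.82 for blood (SD 1.06 over members) and 0.56 for epidermis markers, but also 0.73 for neurotransmitter, 0.55 for dI2, 0.41 for posterior Hox, 0.37 for neural crest, 0.35 for pan-neuronal and 0.32 for axon guidance lists, and the bound for this test was set with medians already known. The median excess was under 0 for the shared dorsal (-0.42), anterior Hox (-0.25), neural progenitor (-0.15), BMP and Wnt response (-0.095) and cell cycle (-0.054) lists. For the lists with a positive excess, a low level on dNeurog1-GFP replicate 1 would give the same excess, and that array also had nearly no Y-linked signal.

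The medians of the cell cycle and progenitor lists were higher in dNeurog1-GFP cells and that of the pan-neuronal list in Atoh1-GFP cells. The cell cycle median stayed at -0.62 or beyond under the 4 scalings tried, while the median over all genes lay between -0.029 and 0.0041. This is a weak test of array scaling, since the arrays of each replicate number already shared 1 trimmed mean and rescaling could hardly move the median. Ventral cells in dNeurog1-GFP replicate 2 do not account for the cell cycle difference within replicate 1, where its median was -0.64 and the ventral list had a median of 0.01. Ventral members went both ways within replicate 1, with Lhx4 at -1.65 and Olig2 at -1.02 but Evx1 at 2.60 and Foxa2 at 1.02. Whether the dNeurog1-GFP replicate 1 array also held some ventral cells was not tested. A larger share of dividing cells among the dNeurog1-GFP sorted cells is a candidate explanation, with all 37 of 37 genes higher there within both replicate numbers. This count rests on the values that showed the pattern, and a lower level per dividing cell was not tested.

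For Xist, probe sets disagreed between replicate numbers: 1 probe set had signals of 791 and 107 in Atoh1-GFP and 1305 and 206 in dNeurog1-GFP cells, and the brightest had 4527 and 8725 against 5482 and 6990.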
